A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

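The series holds 24 Affymetrix yeast arrays, 1 per culture, for 8 strains with 3 biological replicates each. Per the labels the strains were grown aerobically in 1 L bioreactors at 30 °C, pH 5.0, with 10 g/L glucose and a dilution rate of 0.1 per h, and were sampled at steady state. The deposited values are log2 probe-set summaries, made with RMA in the affy package per the submitters' processing notes, which give no versions. The notes do not name the set of arrays or probe sets normalized together. The array medians differ over the deposited probe sets. Scanner files were not used. The number of arrays limits the precision, and 3 per strain leave 16 residual degrees of freedom in the common fit.

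Of 5716 probe sets, 5498 name exactly 1 gene, 0 name several and 218 name none. The 5498 gene identifiers all matched the reference gene table (assembly R64, used for names only), which updated 12 symbols. Where 2 or more probe sets named a gene, the one with the highest mean over all arrays was kept, which left out 49 and left 5449 genes. Among these, 112 have a probe set that the array's design shares between near-identical genes, so which member gave the signal is uncertain. The table holds 0 control probe sets, and 0 of its columns went unused. No filter on low values was applied, and no coordinates are given, since the array's genome build is not named.

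Groups were taken from the sample titles. One linear model with a mean per strain was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), so that the strains share 1 estimate of the spread per gene. Before the data were examined, 15 comparisons were fixed: each deletion strain against the reference, the triple strain against each double strain, an interaction for each pair of genes, and 2 contrasts between double strains. A further 3 comparisons, each single deletion strain against the mean of the other two, were added after the data were seen. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, in two-sided tests, with no minimum fold. The moderated F test over the 7 contrasts with the reference gave the number of genes that differ among strains.

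Gene groups were fixed at the same time, and 35 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a group with all other genes, while fry tests whether the group's own genes move one way. P values were adjusted over the 245 tests against the reference together, and within each other comparison.

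Named genes followed a rule fixed with the comparisons. SIP1, SIP2 and GAL83 came first. For each comparison with the reference, up to 8 called genes each way with the largest changes followed, with the 3 mutant arrays all beyond the 3 reference arrays and a standard name, and up to 5 each way in other comparisons, where interactions carry no rule on arrays. Then came up to 4 called members of each gene group with a camera call or with at least 25% of its genes called, and a fixed panel of genes of carbon source use and lipid synthesis, named whether called or not. Fewer were named in places, always those ranked first.

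Alternatives fixed with the comparisons were median centring, quantile normalization over the tested genes, leaving out the 25% of genes with the lowest means, raising values to the level that bounds these genes (9.746), all probe sets, eBayes with trend and robust, array weights, replicate number as a block, the compared groups alone, and leaving out each replicate in turn. Leaving out 3 doubted arrays together (sip1 sip2 replicate 3, sip1 gal83 replicate 2 and sip2 gal83 replicate 1) was added after the data were seen. No 2 arrays were identical, and the highest correlation between arrays was 0.9987.

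The analysis was tested on simulated data for 5449 genes, with the spread of the fit and known changes. For the sip1 strain against the reference, 76% of genes with a true log2 change of 0.5, 90% at 1 and 100% at 2 were recovered, with 4 false calls among 187. For the triple against the sip2 gal83 strain these were 64%, 94% and 100% with 9 false calls among 188, for the SIP1 GAL83 interaction 50%, 90% and 100% with 8 among 178, and for gal83 against the other single deletion strains 78%, 98% and 100% with 10 among 198.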

Results

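RNA from 24 aerobic, glucose-limited chemostat cultures of budding yeast was measured on Affymetrix arrays, 3 biological replicates for each of 8 strains. Besides the reference strain, these were strains deleted for SIP1, SIP2 or GAL83, for each pair of these genes, and for all 3. The genes encode the alternative β-subunits of the Snf1 kinase, the yeast AMP-activated protein kinase, which is needed for growth on carbon sources other than glucose. The series asks what each β-subunit does and how far one can stand in for another, so the strains were compared with the reference, with each other, and by interaction terms. Values are deposited log2 intensities per probe set, with array medians between 10.90 and 11.07 and lowest values near 1.67. Unless another error is named, changes are log2 differences ± the standard error of the fit to all 24 arrays, with n = 3 arrays per strain, and strain levels are means ± SD.

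The deleted genes read as the labels say in 22 of the 24 arrays. SIP1 (YDR422C) stood at 10.93 ± 0.17 in the reference and 2.03 ± 0.00062 in the sip1 strain, SIP2 (YGL208W) at 10.64 ± 0.082 and 2.03 ± 0.0038 in the sip2 strain, and GAL83 (YER027C) at 11.28 ± 0.038 and 2.08 ± 0.0021 in the gal83 strain. Values near 2 are the lower end of the scale, so a change against them depends on that floor. The array labelled sip1 gal83 replicate 2 gave 9.72 for GAL83, where the strain's other arrays gave about 2.07, and the array labelled sip1 sip2 replicate 3 gave 6.0 for SIP2, where the others gave about 2.02. SIP2 was also 1.08 below the reference in the gal83 strain, which did not pass the test (adjusted p = 0.214). The sip1 sip2 array with SIP2 signal widens the common spread of this gene, and without the 3 doubted arrays, a choice made after the data were seen, the same change passed (adjusted p = 2.79e-09).

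**Figure D1:**
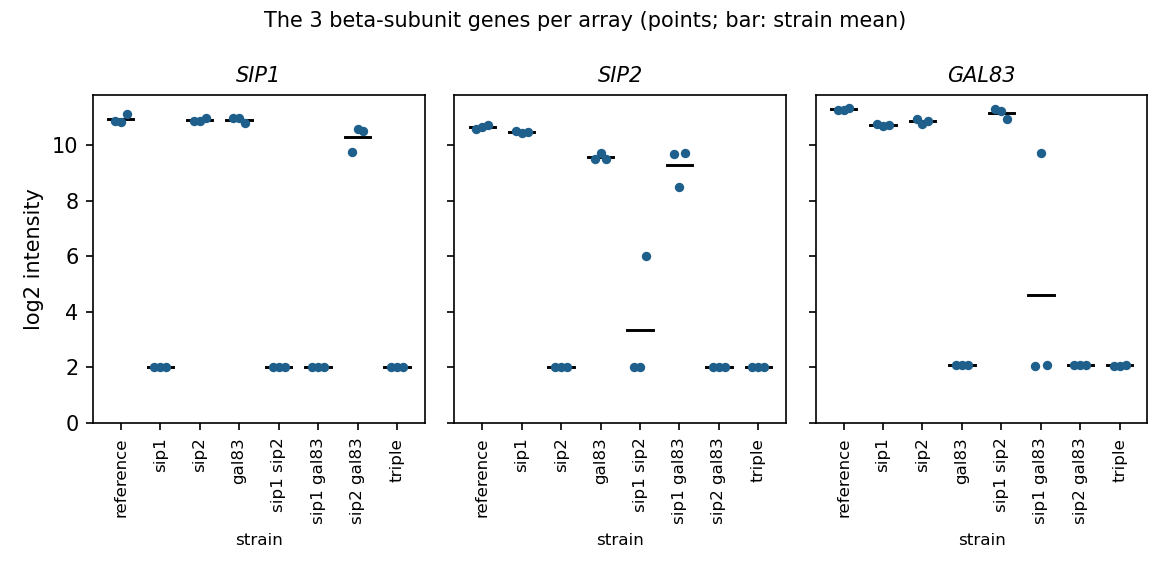
Log2 intensity of SIP1, SIP2 and GAL83 on each of the 24 arrays, grouped by strain, with 1 point per array and a bar at the strain mean. Deleted genes lie near 2, except GAL83 at 9.72 in 1 sip1 gal83 array and SIP2 at 6.0 in 1 sip1 sip2 array.

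Of 5449 genes, 3892 differed among the 8 strains (71.4%, moderated F test). Against the reference, 2148 genes were called in the sip1 strain, 2217 in sip2, 2243 in gal83, 14 in sip1 sip2, 594 in sip1 gal83, 2031 in sip2 gal83 and 2093 in the triple strain. The median change over all genes was -0.0875, -0.12 and -0.0972 in the single deletion strains, so small changes in these strains are best read relative to those shifts. Subtracting each array's median left the number of calls within 1.5 times in each comparison but moved the balance of higher and lower genes in most of them.

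**Figure D2:**
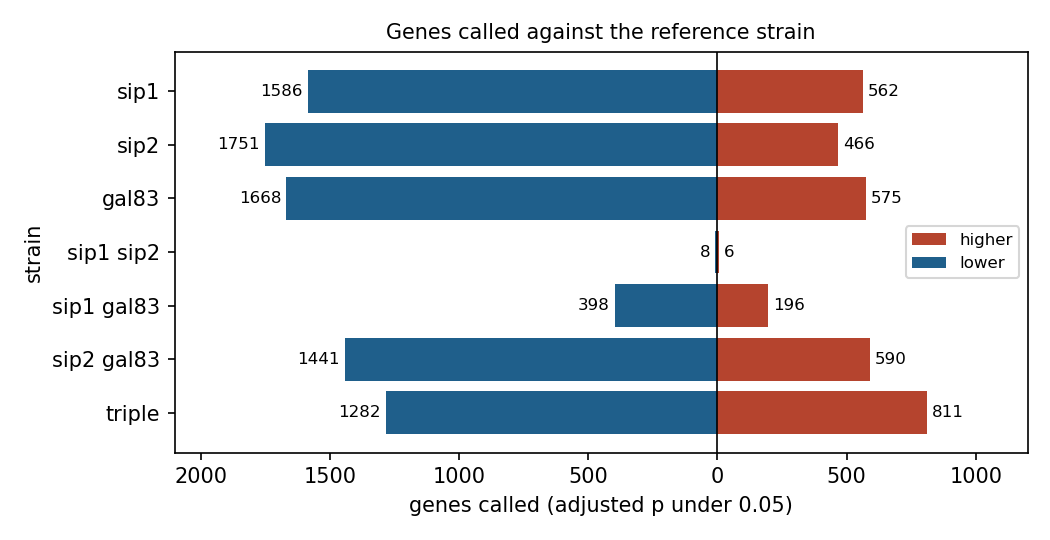
Genes called higher (right) and lower (left) at an adjusted p under 0.05 against the reference strain, of 5449 tested, for each of the 7 deletion strains. The sip1 sip2 strain had 6 genes higher and 8 lower, the fewest of the 7 strains.

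In the sip1 strain the largest fall besides SIP1 itself was in PHO5, the main secreted acid phosphatase, which fell by 6.78 ± 0.47 to 2.08 ± 0.00030, the lower end of the scale. PHO5 was not low in every strain without SIP1. Its arrays read 8.16 to 8.78 in sip1 sip2 and 8.30 to 8.65 in the triple strain. ENT4, an epsin-like protein gene, fell by 3.79 ± 0.43. RPR2, encoding a subunit of RNase P, fell by 3.71 ± 0.36, and RIM9 of the Rim101 signalling pathway fell by 3.52 ± 0.57. The polyamine exporter gene TPO3 rose by 2.08 ± 0.41. PUF3, encoding an RNA-binding protein of messages for mitochondrial proteins, rose by 1.88 ± 0.41, and the hexose transporter gene HXT11 rose by 1.5 ± 0.28. FBP1 and PCK1 of gluconeogenesis, known Snf1 targets, stood at 0.078 ± 0.46 and 0.53 ± 0.39 and did not pass (adjusted p = 0.911 and 0.292). Without the 3 doubted arrays of other strains the same change of PCK1 passed (adjusted p = 0.000625). SUC2, encoding invertase, rose by 0.58 ± 0.15.

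Among the fixed gene groups in the sip1 strain, 65 of 128 cytosolic ribosomal protein genes rose, 4 fell and 59 did not pass (69 higher and 4 lower adjusted over the list alone, camera adjusted p = 3.73e-20, or 0.666 with an estimated correlation). RPL39 stood at 0.76 and RPS10B at 0.72. Of 35 genes of the respiratory chain and ATP synthase, 20 rose and 2 fell (21 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.35e-08, or 0.0962 with an estimated correlation). QCR10 stood at 0.63 and CYC7 at 0.59. The iron regulon, the genes that take up and spare iron, went the other way: 20 of 26 fell and 0 rose (1 higher and 22 lower adjusted over the list alone, camera adjusted p = 0.00271, or 0.8 with an estimated correlation). The siderophore transporter gene SIT1 stood at -3.17 and TIS11 at -3.15. Genes of glycogen and trehalose metabolism fell in 11 of 21 cases (0 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0346, or 0.865 with an estimated correlation). PIG2 fell by 0.68 and the trehalase gene NTH1 fell by 0.55. Of 23 genes for thiamine, biotin and other vitamins, 14 fell and 1 rose. Adjusted over the list alone, 1 was higher and 16 lower (camera adjusted p = 0.0224, or 0.666 with an estimated correlation). SNO1 stood at -1.51. The glycogen call ended without reference replicate 2 or 3 or sip1 replicate 2 (adjusted p = 0.0575, 0.0705 and 0.106). The call of the vitamin group ended without sip1 replicate 2 (adjusted p = 0.0747). In all, 562 genes were higher and 1586 lower, and after subtracting array medians 1272 were higher and 1024 lower.

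The sip2 strain shared 1312 lower and 398 higher genes with the sip1 strain, where independent lists would share 510 and 48.1. Both comparisons use the same 3 reference arrays, and part of the excess can come from them. Across genes, which are not independent, the changes correlated at 0.837 with a covariance of 0.176, where simulated data without effects gave 0.499 and 0.0101. Between these strains 0 genes were called in opposite directions. RIM9 fell by 4.07 ± 0.57, ENT4 fell by 4.0 ± 0.43, RPR2 fell by 3.79 ± 0.36 and the vacuolar lipase gene ATG15 fell by 3.53 ± 0.73. TPO3 rose by 1.65 ± 0.41, SUS1, encoding a part of the SAGA and TREX-2 complexes, by 1.43 ± 0.17, and the signal peptidase gene SPC1 by 1.41 ± 0.15. FBP1, at 0.21 ± 0.46, and PCK1, at 0.28 ± 0.39, did not pass (adjusted p = 0.764 and 0.604). Without the 3 doubted arrays the same change of PCK1 passed (adjusted p = 0.0283). SUC2 rose by 0.61 ± 0.15, and UPC2, encoding a sterol regulator, fell by 0.66 ± 0.17.

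In the sip2 strain 65 of 128 cytosolic ribosomal protein genes rose and 4 fell (70 higher and 6 lower adjusted over the list alone, camera adjusted p = 5.02e-23, or 0.666 with an estimated correlation). RPL39 stood at 0.71. The respiratory chain rose in 18 of 35 genes and fell in 3 (18 higher and 4 lower adjusted over the list alone, camera adjusted p = 1.43e-07, or 0.0962 with an estimated correlation). CYT1, encoding cytochrome c1, fell by 0.63 and QCR10 rose by 0.59. The iron regulon fell in 17 of 26 genes and rose in 0 (0 higher and 20 lower adjusted over the list alone, camera adjusted p = 0.0168, or 0.867 with an estimated correlation). SIT1 stood at -2.38 and ENB1 at -2.04, both siderophore transporter genes. The SIT1 call ended without reference replicate 2 or 3 or sip2 replicate 3 (adjusted p = 0.113, 0.117 and 0.152), and that of the iron regulon without reference replicate 3 (adjusted p = 0.054). In total 466 genes were higher and 1751 lower, against 1247 and 1004 after subtracting array medians.

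In the gal83 strain the largest falls among gluconeogenic and glyoxylate genes were in FBP1, MLS1, PCK1 and ICL1. FBP1 (YLR377C), encoding fructose-1,6-bisphosphatase, fell by 3.52 ± 0.46 from 12.11 ± 0.22 to 8.59 ± 0.49. MLS1 (malate synthase) fell by 3.35 ± 0.55, PCK1 (phosphoenolpyruvate carboxykinase) fell by 2.69 ± 0.39 and ICL1 (isocitrate lyase) fell by 2.50 ± 0.45. Of the 14 genes of this group 9 fell and 0 rose (0 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00957, or 0.699 with an estimated correlation). SIP4, encoding an activator of these genes, fell by 0.91 ± 0.28. CAT8, encoding another activator, stood at 0.014 ± 0.056 (adjusted p = 0.864). ADH2 and ACS1, other genes of non-fermentable carbon use, stood at -0.094 ± 0.042 and -0.0011 ± 0.10 and did not pass (adjusted p = 0.082 and 0.995). Without the 3 doubted arrays ADH2 passed (adjusted p = 0.043), but its change was close to the strain's median change over all genes, -0.0972. JEN1 fell by 0.19 ± 0.059, and SUC2 rose by 0.98 ± 0.15. The JEN1 call ended without reference replicate 2 or 3 or gal83 replicate 1 or 2 (adjusted p = 0.0579, 0.0993, 0.0606 and 0.0572). The SIP4 call ended without gal83 replicate 2 or 3 (adjusted p = 0.0512 and 0.0564).

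The largest rises in the gal83 strain included PAU18 at 2.19 ± 0.37, PAU14 at 1.88 ± 0.27, PAU24 at 1.88 ± 0.21 and DAN1 at 1.53 ± 0.27. The probe sets of PAU18, PAU14 and PAU24 are shared with near-identical genes, so the member is uncertain. Of the 14 genes in the group of anaerobic genes and cell wall mannoproteins 2 rose (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.103, or 0.865 with an estimated correlation). UPC2, encoding a known activator of DAN1, rose by 0.71 ± 0.17. Of 18 phosphate regulon genes 11 fell and 0 rose (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.0237, or 0.666 with an estimated correlation). The transporter gene PHO84 stood at -2.63. The iron regulon had a median change of -0.635 in gal83, beside -0.807 in sip1 and -0.838 in sip2. After subtracting array medians these were -0.519, -0.703 and -0.7. The groups that rose in the other single deletion strains rose here too. Of the 128 cytosolic ribosomal protein genes 65 rose and 5 fell (68 higher and 6 lower adjusted over the list alone, camera adjusted p = 2.12e-19, or 0.666 with an estimated correlation). RPL39 stood at 0.72. Of 35 respiratory genes 18 rose and 1 fell (19 higher and 3 lower adjusted over the list alone, camera adjusted p = 3.12e-07, or 0.0962 with an estimated correlation). CYC7 stood at 1.02. In all 575 genes were higher and 1668 lower, against 1263 and 997 after subtracting array medians.

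**Figure D3:**
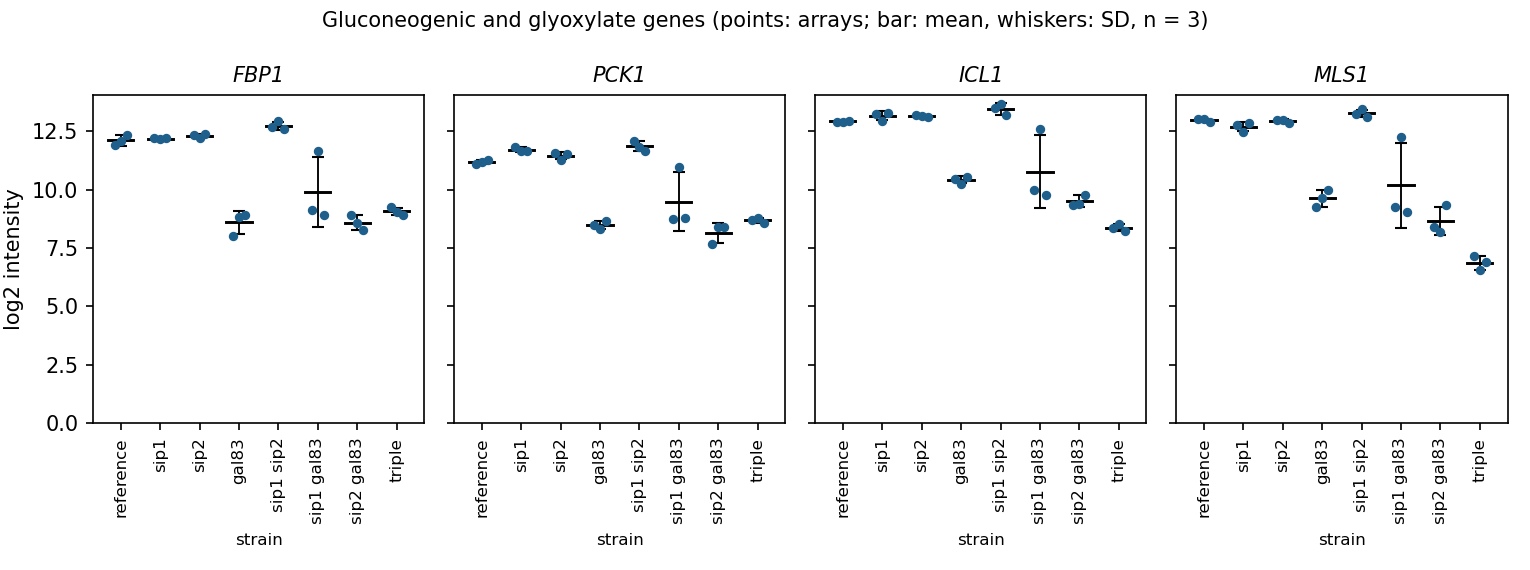
Log2 intensity of FBP1, PCK1, ICL1 and MLS1 by strain, with 1 point per array and the mean ± SD of 3 arrays. The 4 genes lie lower in each strain that lacks GAL83, and the array labelled sip1 gal83 replicate 2 lies between the levels of that strain's other arrays and of the reference.

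The 3 single deletion strains shared many changes: 1128 genes were lower and 343 higher in all 3, where independent lists would share 156 and 5.07. Chromosome replication gene SLD7 fell by 3.18 ± 0.40 in sip1, fell by 3.52 ± 0.40 in sip2 and fell by 3.18 ± 0.40 in gal83, to levels near the floor, and ENT4 fell by 3.42 ± 0.43 in gal83. Part of this overlap can come from the 3 reference arrays that all the comparisons share. When each strain was given a reference array of its own, a test chosen after the data were seen, 472 to 507 of the 1471 genes were still called alike over the 6 ways to do so, with less power from 1 array each. The spread for these single reference arrays came from the replicates of other strains. The genes had been picked as alike, and no value without effects was run beside this count. Across genes, which are not independent, the covariance of the changes was 0.176, 0.157 and 0.156 for the 3 pairs of strains, beside 0.0101, 0.0103 and 0.01 in simulated data without effects that share the reference. After subtracting array medians 625 genes were lower and 908 higher in all 3, so the balance turned from mostly lower to mostly higher. Of the 1471 genes called alike, picked for their changes in the single strains, the lower ones had a median change of -0.432, -0.486 and -0.453 in the single deletion strains. It was -0.0688 in sip1 sip2, -0.0872 in sip1 gal83, -0.239 in sip2 gal83 and -0.19 in the triple strain.

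Because of these shared changes, each single deletion strain was also compared with the mean of the other two, comparisons chosen after the data were seen. Here the gal83 strain stood out with 122 genes higher and 82 lower (113 and 81 after subtracting array medians). FBP1 fell by 3.66 ± 0.40, MLS1 fell by 3.19 ± 0.48, PCK1 fell by 3.10 ± 0.33 and ICL1 fell by 2.73 ± 0.39. In all 8 of 14 gluconeogenic and glyoxylate genes fell (0 higher and 8 lower adjusted over the list alone, camera adjusted p = 7.37e-13, or 0.0515 with an estimated correlation). The carnitine shuttle gene YAT1 fell by 1.51 ± 0.15 and YAT2 fell by 0.72 ± 0.086. In all 3 of 11 genes of that transport group fell (0 higher and 5 lower adjusted over the list alone, camera adjusted p = 1.58e-06, or 0.308 with an estimated correlation). Maltose and sucrose genes rose in 4 of 10 cases (6 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.58e-06, or 0.0963 with an estimated correlation). MAL31 rose by 0.78. The group of anaerobic genes and cell wall mannoproteins rose in 3 of 14 cases (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000264, or 0.494 with an estimated correlation). DAN1 stood at 1.89. Ergosterol genes rose in 5 of 24 cases (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 8.6e-05, or 0.504 with an estimated correlation). UPC2 rose by 1.05 ± 0.15. The count of 204 fell to 95 without gal83 replicate 1.

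The sip1 strain differed from the other single deletion strains in 79 genes, 38 higher and 41 lower (27 and 54 after subtracting array medians). The sip2 strain differed in 100, 27 higher and 73 lower (31 and 50). PHO5 fell by 5.97 ± 0.41 in sip1 and OYE3, an NADPH dehydrogenase gene, fell by 1.5 ± 0.18. PCK1 was higher by 1.73 ± 0.33, a difference that includes its fall in gal83. In sip2, PAU14, with a shared probe set, was lower by 3.08 ± 0.23 and FBP1 was higher by 1.92 ± 0.40, again against a mean that holds the gal83 strain. The PCK1 call ended without sip1 replicate 1 or 2 (adjusted p = 0.0741 and 0.06). The FBP1 call ended without sip2 replicate 1, 2 or 3 (adjusted p = 0.101, 0.0736 and 0.0669). The sip1 count was 27, 21 and 142 without sip1 replicate 1, 2 and 3, and 149 without gal83 replicate 3. The sip2 count was 26 and 29 without sip2 replicate 1 and 2, and 61 without gal83 replicate 1.

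In the sip1 sip2 strain, which keeps GAL83, 14 genes were called against the reference, 6 higher and 8 lower (8 and 9 after subtracting array medians). Besides SIP1 and SIP2, NFT1, an ABC transporter gene, fell by 1.64 ± 0.28 to 2.37 ± 0.41, near the floor. GTO3, a glutathione transferase gene, fell by 1.14 ± 0.17, and the amino acid sensor gene SSY1 fell by 0.43 ± 0.053. The cell wall mannoprotein gene CWP1 rose by 0.70 ± 0.11, and IMD2 and ASP3-1, whose probe sets are shared with near-identical genes, rose by 0.84 ± 0.17 and 0.43 ± 0.058. FBP1, at 0.63 ± 0.46, PCK1, at 0.69 ± 0.39, and ICL1, at 0.53 ± 0.45, did not pass (adjusted p = 0.768, 0.64 and 0.825). Without the 3 doubted arrays PCK1, at 0.79, and ICL1, at 0.66, passed as higher (adjusted p = 0.00219 and 0.034). SUC2, at 0.13 ± 0.15, did not pass either (adjusted p = 0.912). At an unadjusted p under 0.05 the genes numbered 506. The NFT1 call ended without reference replicate 2 or sip1 sip2 replicate 1 or 3 (adjusted p = 0.0546, 0.0547 and 0.0669). The IMD2 call ended without reference replicate 1 or 2 or sip1 sip2 replicate 1, 2 or 3 (adjusted p = 0.217, 0.267, 0.0899, 0.134 and 0.0606), and without the 3 doubted arrays (adjusted p = 0.0525). The count was 5 when the genes with the lowest 25% of means were left out or when the compared groups alone were fitted. It was 160 with array weights and 41 without the 3 doubted arrays, a choice made after the data were seen.

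The sip1 gal83 strain had lower gluconeogenic genes, as gal83 did. MLS1 fell by 2.80 ± 0.55, FBP1 fell by 2.21 ± 0.46, ICL1 fell by 2.15 ± 0.45 and PCK1 fell by 1.68 ± 0.39. In all 7 of 14 genes of the group fell and 1 rose (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.000788, or 0.666 with an estimated correlation). PHO5 fell by 5.84 ± 0.47 and GTO3 fell by 3.02 ± 0.17, to 3.02 ± 1.64 and 2.19 ± 0.11, near the floor. The acetate transporter gene ADY2 fell by 2.05 ± 0.39. In all 6 of 11 carnitine, acetate and lactate transport genes fell (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 4.48e-05, or 0.666 with an estimated correlation). Peroxisomal genes fell in 8 of 20 cases (0 higher and 13 lower adjusted over the list alone, camera adjusted p = 4.48e-06, or 0.666 with an estimated correlation). PEX18 fell by 1.17 and ECI1, for fatty acid oxidation, fell by 0.99. Stress genes controlled by Msn2 and Msn4 fell in 12 of 30 cases (0 higher and 21 lower adjusted over the list alone, camera adjusted p = 8.45e-10, or 0.666 with an estimated correlation). The catalase gene CTT1 fell by 1.11. The PCK1 call ended without sip1 gal83 replicate 1 or 3 (adjusted p = 0.0541 and 0.0715). The PEX18 call ended without reference replicate 2 or sip1 gal83 replicate 3 (adjusted p = 0.0604 and 0.0844).

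Higher in the sip1 gal83 strain were PAU14 and PAU8, with shared probe sets, at 2.47 ± 0.27 and 2.27 ± 0.23. ATF2, an alcohol acetyltransferase gene, rose by 1.90 ± 0.35, and YSR3, a sphingolipid phosphatase gene, rose by 1.74 ± 0.28. Ergosterol synthesis genes rose in 12 of 24 cases and fell in 1 (14 higher and 2 lower adjusted over the list alone, camera adjusted p = 5.67e-10, or 0.606 with an estimated correlation). ERG26 rose by 0.49 and MVD1 by 0.47. The genes ERG11 and ERG1, at 0.048 ± 0.046 and 0.084 ± 0.079, did not pass (adjusted p = 0.583 and 0.569). In all 196 genes were higher and 398 lower, against 229 and 330 after subtracting array medians. Without the array that carried GAL83 signal, and with the other doubted arrays left out after the data were seen, 333 were higher and 565 lower. There MLS1 fell by 3.85, FBP1 fell by 3.08, ICL1 fell by 3.04 and PCK1 fell by 2.42. The count was 231 without sip1 gal83 replicate 3, 335 and 350 without reference replicate 2 and 3, and 1594 with array weights.

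The sip2 gal83 strain had lower gluconeogenic genes too. MLS1 fell by 4.34 ± 0.55, FBP1 fell by 3.53 ± 0.46, ICL1 fell by 3.41 ± 0.45 and PCK1 fell by 3.02 ± 0.39. In all 11 of 14 genes fell and 0 rose (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 3.03e-05, or 0.666 with an estimated correlation). SIP4 fell by 1.92 ± 0.28. Carnitine, acetate and lactate transport genes fell in 10 of 11 cases (0 higher and 10 lower adjusted over the list alone, camera adjusted p = 6.21e-05, or 0.666 with an estimated correlation). YAT1 fell by 1.63. The tricarboxylic acid cycle fell in 11 of 16 genes (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.00207, or 0.685 with an estimated correlation). KGD1 fell by 0.52. Glycogen and trehalose metabolism fell in 17 of 21 genes (1 higher and 18 lower adjusted over the list alone, camera adjusted p = 0.000236, or 0.666 with an estimated correlation). GAC1, for a regulator of glycogen synthesis, fell by 2.20. Stress genes fell in 18 of 30 cases (0 higher and 18 lower adjusted over the list alone, camera adjusted p = 0.000788, or 0.86 with an estimated correlation). CTT1 fell by 1.73. Of 27 genes of nitrogen source use 15 fell and 1 rose (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 0.00679, or 0.666 with an estimated correlation). DAL2 fell by 1.76. Without sip2 gal83 replicate 1, GAC1 fell by 1.08 and KGD1 fell by 0.33.

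Ergosterol genes rose in 10 of 24 cases in the sip2 gal83 strain and fell in 2 (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.22e-06, or 0.666 with an estimated correlation). ERG28 stood at 0.47 and HMG2, for an isozyme of HMG-CoA reductase, at -0.57. UPC2 rose by 0.81 ± 0.17. Of 14 anaerobic and cell wall mannoprotein genes 5 rose (5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0098, or 0.699 with an estimated correlation). DAN1 rose by 1.68. Of 128 cytosolic ribosomal protein genes 75 rose and 1 fell (77 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.45e-21, or 0.666 with an estimated correlation). RPS19A rose by 0.53. SLZ1, for a part of the meiotic RNA methyltransferase, rose by 3.66 ± 0.89 from the floor, but its 3 arrays spread from 1.95 to 7.69. The glutamate and aspartate permease gene DIP5 rose by 2.76 ± 0.53. In all 590 genes were higher and 1441 lower, against 1185 and 980 after subtracting array medians. The call of the anaerobic and mannoprotein group ended without sip2 gal83 replicate 2 (adjusted p = 0.106). The count was 528 when the compared groups alone were fitted. The 3 sip2 gal83 arrays had residual SDs of 0.294, 0.179 and 0.177, where arrays of the other strains had 0.0858 to 0.174. The common fit assumes 1 spread per gene for all strains. Its errors for sip2 gal83 may therefore be too small and its counts too high, in the comparisons with this strain below as well.

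The triple strain had the lowest levels of MLS1 and ICL1, where MLS1 fell by 6.12 ± 0.55 and ICL1 fell by 4.56 ± 0.45. FBP1 fell by 3.04 ± 0.46 and PCK1 fell by 2.49 ± 0.39. Of the 14 gluconeogenic and glyoxylate genes 8 fell and 3 rose (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0276, or 0.752 with an estimated correlation). The isomaltase gene IMA5 fell by 5.16 ± 0.27 and ANS1, for a predicted cell wall protein, fell by 6.68 ± 0.41. SUC2 rose by 0.53 ± 0.15, ADH2 fell by 0.32 ± 0.042 and JEN1 fell by 0.28 ± 0.059. ACS1, at 0.034 ± 0.10, did not pass (adjusted p = 0.846). Carnitine, acetate and lactate transport fell in 8 of 11 genes (0 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.000753, or 0.666 with an estimated correlation). YAT2 fell by 2.31.

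The largest rises in the triple strain included genes of early meiosis, which haploid cells growing on glucose keep off. SLZ1 rose by 9.04 ± 0.89 from 1.93 ± 0.0012, the lower end of the scale, to 10.97 ± 0.42. REC104 and REC102, for partners of the meiotic nuclease Spo11, rose by 5.44 ± 0.34 and 4.34 ± 0.26. The recombination gene SAE3 rose by 5.26 ± 0.24 and PHO92, for a reader of methylated messages, rose by 5.08 ± 0.21. REC102, SAE3 and PHO92 stood at 2.02 ± 0.014, 2.41 ± 0.035 and 2.31 ± 0.033 in the reference, at the floor, so the sizes of these rises depend on it. Of the 26 sporulation and meiosis genes 8 rose and 3 fell (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0249, or 0.752 with an estimated correlation). The kinase gene IME2 rose by 4.34 ± 0.34, SPO11 by 3.69 ± 0.30 and AMA1 by 3.43 ± 0.26, the last 2 from 2.14 ± 0.0042 and 2.31 ± 0.37, at the floor as well. The call of the group ended without triple strain replicate 1 (adjusted p = 0.0521). The subtelomeric gene COS12 rose by 6.12 ± 0.36, the RNA-binding protein gene RNP1 by 5.56 ± 0.38 and the amino acid permease gene BAP3 by 4.79 ± 0.42, from 2.08 ± 0.00062, 2.13 ± 0.0028 and 2.09 ± 0.0022, again at the floor.

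**Figure D4:**
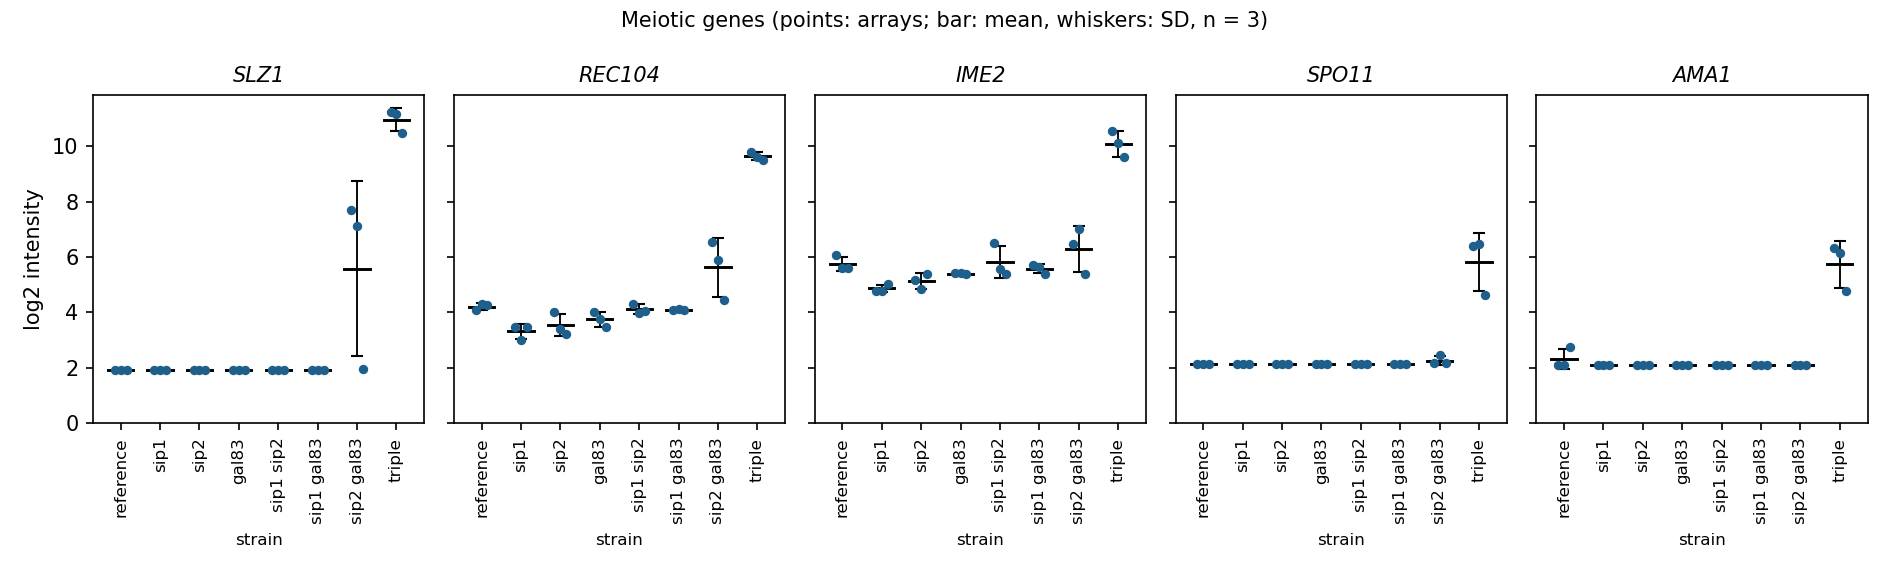
Log2 intensity of SLZ1, REC104, IME2, SPO11 and AMA1 by strain, with 1 point per array and the mean ± SD of 3 arrays. IME2 averaged 10.09 in the triple strain and 5.75 in the reference, and 2 of the 3 sip2 gal83 arrays lay above 7 for SLZ1.

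The triple strain shared 875 lower and 380 higher genes with the sip2 gal83 strain, where independent lists would share 339 and 87.8. Here too the reference arrays are shared, and part of the excess can come from them. The changes correlated at 0.726 across genes with a covariance of 0.202, where simulated data without effects gave 0.505 and 0.0102. Stress genes fell in 23 of 30 cases and rose in 0 (0 higher and 26 lower adjusted over the list alone, camera adjusted p = 2.7e-10, or 0.666 with an estimated correlation). CTT1 fell by 2.15 and SOL4 fell by 1.42. Glycogen and trehalose genes fell in 16 of 21 cases (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 6.77e-05, or 0.666 with an estimated correlation). GAC1 fell by 2.68. Ergosterol genes rose in 14 of 24 cases and fell in 3 (15 higher and 3 lower adjusted over the list alone, camera adjusted p = 4.75e-05, or 0.666 with an estimated correlation). ERG4 rose by 0.69 and MVD1 by 0.52. Of 14 anaerobic and cell wall mannoprotein genes 5 rose and 1 fell (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0224, or 0.752 with an estimated correlation). CWP1, a group member known from aerobic cells, rose by 1.77, and TIR1, known from anaerobic cells, rose by 1.52. The lipid synthesis panel was mixed. ACC1 fell by 0.32 ± 0.064 and HMG1 fell by 0.23 ± 0.060. INO1 and ERG3 rose by 0.49 ± 0.12 and 0.28 ± 0.058, and OLE1, at 0.012 ± 0.037, did not pass (adjusted p = 0.848). In all 811 genes were higher and 1282 lower, against 1191 and 923 after subtracting array medians. The count was 3392 with array weights.

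For the role of the last remaining β-subunit, the triple strain was compared with each double strain. The labels name no batch, so a batch that differs between the strains compared cannot be told apart from the deletion. The genes lower in all 3 single deletion strains had a median change of -0.19 in the triple strain and -0.0688 in sip1 sip2. In the triple strain 1748 genes differed from sip1 sip2, which keeps GAL83. Of these, 766 were higher and 982 lower (960 and 802 after subtracting array medians). MLS1 fell by 6.40 ± 0.55, ICL1 fell by 5.08 ± 0.45 and ANS1 fell by 6.59 ± 0.41. In all 8 of 14 gluconeogenic and glyoxylate genes fell and 2 rose (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00137, or 0.513 with an estimated correlation). SLZ1, at the floor in sip1 sip2, rose by 9.04 ± 0.89 and REC104 by 5.53 ± 0.34. Of 24 ergosterol genes 15 rose and 3 fell (17 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.000302, or 0.513 with an estimated correlation). ERG4 rose by 0.62. The count was 2658 with array weights.

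Against sip1 gal83, which keeps SIP2, 717 genes differed in the triple strain, 328 higher and 389 lower (489 and 253 after subtracting array medians). SLZ1, at the floor in sip1 gal83, rose by 9.04 ± 0.89, REC104 by 5.56 ± 0.34 and PHO5 by 5.42 ± 0.47. PHO5 lay at the floor in sip1 gal83 too, except in the doubted replicate 2, at 4.92. The triple strain, at 8.30 to 8.65, lay near the reference, at 8.85 to 8.87. The difference thus comes from the low level in sip1 gal83, and its cause was not tested. Its rise was 6.36 without the 3 doubted arrays. ANS1 fell by 5.28 ± 0.41 and IMA5 fell by 3.96 ± 0.27. In all 10 of 26 sporulation genes rose and 1 fell (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.1e-06, or 0.387 with an estimated correlation). IME2 rose by 4.52. MLS1 fell by 3.32 ± 0.55, and fell by 2.27 when the doubted arrays were left out after the data were seen. Stress genes fell in 13 of 30 cases (0 higher and 18 lower adjusted over the list alone, camera adjusted p = 1.1e-06, or 0.699 with an estimated correlation). CTT1 fell by 1.03. Leaving out sip1 gal83 replicate 1 or 2 gave 382 or 379 calls. Leaving out triple strain replicate 1, 2 or 3 gave 467, 413 or 448. Array weights gave 2248 and the compared groups alone 1109.

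Against sip2 gal83, which keeps SIP1, 789 genes differed in the triple strain, 520 higher and 269 lower (497 and 290 after subtracting array medians). RNP1 rose by 5.55 ± 0.38, SLZ1 by 5.38 ± 0.89 and PHO92 by 4.93 ± 0.21, with RNP1 and PHO92 at 2.14 ± 0.00055 and 2.45 ± 0.17 in sip2 gal83, at the floor. In all 11 of 26 sporulation genes rose and 1 fell (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000491, or 0.506 with an estimated correlation). REC104 rose by 4.02. ANS1 fell by 5.53 ± 0.41 and IMA5 fell by 2.69 ± 0.27. Without sip2 gal83 replicate 3 the rise of SLZ1 was 3.57. Sulfate and methionine genes rose in 14 of 27 cases (16 higher and 0 lower adjusted over the list alone, camera adjusted p = 5.81e-07, or 0.478 with an estimated correlation). STR3 rose by 0.76. Genes of amino acid synthesis under Gcn4 rose in 16 of 43 cases (24 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.92e-06, or 0.554 with an estimated correlation). HOM3 rose by 0.49. The count was 492 without triple strain replicate 2, 232 with the compared groups alone and 2026 with array weights.

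Interaction terms, the change in a double strain minus the sum of the changes in its single strains, were called for 2854 genes for SIP1 and SIP2, 2793 for SIP1 and GAL83 and 2602 for SIP2 and GAL83. ENT4 had terms of 7.46 ± 0.60, 6.21 ± 0.60 and 5.30 ± 0.60. RPR2 had terms of 7.10 ± 0.51, 5.50 ± 0.51 and 4.70 ± 0.51, and TPO3 had terms of -3.23 ± 0.58, -3.72 ± 0.58 and -3.21 ± 0.58, each against its change in the single strains. PHO5 had a term of 7.40 ± 0.67 for SIP1 and SIP2, since it stood at 8.53 ± 0.33 in the double strain and at the floor in sip1. In the triple strain, which lacks SIP1 as well, PHO5 read 8.30 to 8.65, so its floor level did not follow the loss of SIP1. The positive terms outnumbered the negative, 2122 to 732, 1995 to 798 and 1846 to 756. Subtracting array medians turned this to 1358 and 1593, 1280 and 1606, and 1216 and 1516.

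By group, the iron regulon had positive terms in 22, 22 and 23 of 26 genes for the SIP1 SIP2, SIP1 GAL83 and SIP2 GAL83 pairs (22 higher and 1 lower adjusted over the list alone). SIT1 stood at 6.26, 4.83 and 5.50, and the ferric reductase gene FRE4 was negative at -4.65, -4.84 and -5.59. Camera gave adjusted p = 0.000705, 0.00828 and 0.0019, and adjusted p = 0.742, 0.86 and 0.853 with an estimated correlation. The respiratory chain had negative terms in 19, 18 and 18 of 35 genes (4 higher and 19 lower adjusted over the list alone). COX9 stood at -0.84, -0.79 and -0.90. Camera gave the group adjusted p = 3.31e-07, 6.89e-06 and 1.95e-07, and adjusted p = 0.0426, 0.0959 and 0.0373 with an estimated correlation. Cytosolic ribosomal protein genes had negative terms in 79, 72 and 56 of 128 (9 higher and 79 lower adjusted over the list alone). RPL39 stood at -1.20, -1.27 and -0.96. Camera gave the group adjusted p = 8.99e-21, 2.91e-15 and 2.24e-09, and adjusted p = 0.554, 0.86 and 0.853 with an estimated correlation. The counts adjusted over the list alone are those for the SIP1 SIP2 pair.

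Set side by side, the sip2 gal83 strain, with SIP1 alone, and the sip1 gal83 strain, with SIP2 alone, differed in 683 genes, 150 higher and 533 lower in sip2 gal83 (310 and 273 after subtracting array medians). PHO5 was higher by 5.0 ± 0.47 and SLZ1 by 3.66 ± 0.89, both at or near the floor in sip1 gal83. The amino acid permease gene AGP3 was lower by 2.10 ± 0.46 and the hexose transporter gene HXT4 was lower by 1.88 ± 0.17. Gluconeogenic and glyoxylate genes were lower in 5 of 14 cases (0 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00134, or 0.712 with an estimated correlation). PCK1 was lower by 1.34 ± 0.39 and stood at -0.36 without the 3 doubted arrays (adjusted p = 0.121). The SLZ1 call ended without sip1 gal83 replicate 1 or 2 or sip2 gal83 replicate 1 (adjusted p = 0.058, 0.0527 and 0.0723), and the AGP3 call without sip1 gal83 replicate 2 (adjusted p = 0.0533). Without the 3 doubted arrays both calls ended (adjusted p = 0.156 and 0.153). The PCK1 call ended without sip1 gal83 replicate 2 or sip2 gal83 replicate 1 (adjusted p = 0.0645 and 0.134). The count was 183 without the 3 doubted arrays, a choice made after the data were seen, 4 with the compared groups alone and 1372 with array weights. It was 189 and 235 without sip1 gal83 replicate 1 and 2, and 335, 1209 and 1076 without sip2 gal83 replicate 1, 2 and 3.

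Between the sip2 gal83 strain and the sip1 sip2 strain, with GAL83 alone, 1663 genes differed, 540 higher and 1123 lower in sip2 gal83 (781 and 868 after subtracting array medians). MLS1 was lower by 4.62 ± 0.55, FBP1 was lower by 4.16 ± 0.46, ICL1 was lower by 3.94 ± 0.45 and PCK1 was lower by 3.71 ± 0.39. In all 10 of 14 genes of the group were lower (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 1.64e-07, or 0.385 with an estimated correlation). Carnitine, acetate and lactate transport was lower in 9 of 11 genes (0 higher and 9 lower adjusted over the list alone, camera adjusted p = 1.04e-05, or 0.486 with an estimated correlation). YAT1 was lower by 1.99. SLZ1, at the floor in sip1 sip2, and DIP5 were higher by 3.66 ± 0.89 and 3.19 ± 0.53. The SLZ1 call ended without the 3 doubted arrays (2.60, adjusted p = 0.0732). The count was 210 with the compared groups alone and 1091 without the 3 doubted arrays.

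The α-specific genes were high in each strain, with strain means of 14.8 to 15.1 for MF(ALPHA)1 and 12.5 to 12.9 for STE3. The changes below are therefore not read as a change of mating type. Of the a-specific genes in the reference, MFA2 and ASG7 lay at the floor (2.04 and 1.95) and the others between 4.82 and 9.65. Of the mating-type genes, STE2, the α-factor receptor gene of a cells, fell by 2.50 ± 0.30 and AGA2 fell by 2.60 ± 0.52 in the triple strain. There 3 of 7 a-specific genes fell (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.162, or 0.715 with an estimated correlation). Of the α-specific genes, MF(ALPHA)2 stood at 12.69 ± 0.38 in the reference and 13.73 ± 0.096 in the triple strain (adjusted p = 0.00147). SAG1 went from 12.52 ± 0.36 to 12.96 ± 0.084, STE3 from 12.69 ± 0.14 to 12.91 ± 0.066 and MF(ALPHA)1 from 15.03 ± 0.095 to 15.07 ± 0.021, and these did not pass (adjusted p = 0.0739, 0.136 and 0.648). In the sip1 gal83 strain 3 of 7 fell (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0249, or 0.666 with an estimated correlation). STE2 fell by 1.81 ± 0.30. The call of the group in sip1 gal83 ended without reference replicate 2 (adjusted p = 0.0542). Over the 245 tests of 35 gene groups against the reference, 51 passed with camera's preset correlation, 26 higher and 25 lower. With quantile normalization 61 passed, 18 higher and 43 lower, and with fry 113 passed, 18 higher and 95 lower. Of the 51, 0 held with an estimated correlation.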

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

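The tests of the shared single-strain pattern below were chosen after that pattern was seen; the regroupings of arrays were planned. An interaction term is the change in a double strain minus the sum of the changes in its single strains, and 2854 genes were called for SIP1 and SIP2, 2793 for SIP1 and GAL83 and 2602 for SIP2 and GAL83. Of 100 regroupings of the arrays compared, 1 gave as many calls in each case, the real one. The highest others gave 1577, 2691 and 1455. These regroupings mix arrays of all strains in a term, so changes in the single strains alone can set the real grouping apart. They therefore cannot decide whether the interactions exceed chance. For SIP1 and GAL83 the count was 2517 to 2674 when 1 replicate was left out, below the 2691 of another regrouping. That other regroupings call so many genes points to a structure of the samples.

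Of the 1471 genes called alike in the 3 single deletion strains, such as ENT4, which fell in each of them, and TPO3, which rose in each, 1457, 1443 and 1332 were called in these interactions, whose terms subtract the same single-strain changes, and they made up 51.1%, 51.7% and 51.2% of the interaction calls. A difference in array-wide level is argued against as the sole source, since 65.8% of these genes were still called alike after array medians were subtracted, although this subtraction, which moves all genes of an array alike, took the genes lower in all 3 strains from 1128 to 625 and those higher in all 3 from 343 to 908. Reference arrays that alone stand apart are argued against, since 66.8% were called alike when the sip1 sip2 arrays took the place of the reference. Only 14 genes were called in sip1 sip2 against the reference. If both strains stood apart together, the swap would give nearly the same calls, so it cannot decide on that case. Of the genes called in any single strain, 48.9% were alike in all 3; a batch of cultures or arrays that held the single deletion strains may have produced this, and such a batch would also give interaction terms without any dependence of 1 gene on another. It cannot be told apart from a response of cells to 1 missing subunit, which stays open as well, because the labels name no batch. The pattern was not confined to the single strains. The lower and higher genes had median changes of -0.239 and 0.181 in sip2 gal83 and -0.19 and 0.14 in the triple strain. In sip1 sip2 these were -0.0688 and 0.0697, and in sip1 gal83 -0.0872 and 0.096. A batch or response limited to the single strains would not by itself give the shifts in sip2 gal83 and the triple strain.

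Of 218 probe sets that name no gene, outside the genes tested, 93 were called in the triple strain against the reference (42.7%), 34 higher and 59 lower, where 38.4% of the genes tested were called.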

How the results depend on the processing

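Leaving out the 3 doubted arrays was chosen only after the data were seen. Of 203 called results for named genes, 99 kept their call and direction under every alternative run and 0 reversed. Raising low values to 9.746, the level bounding the lowest 25% of genes, ended 86 of the calls, a setting that removes changes below that level by construction, fitting the compared groups alone ended 29, and quantile normalization ended 4. Leaving out the 3 doubted arrays ended 5 of the calls, array weights 3, median centring 2 and the replicate block 1. Of named results that were not called, 6 passed without the 3 doubted arrays. Signal near the floor is what these arrays limit: folds against values near 2 depend on it. The labels give no shared origin to arrays of one replicate number, and the mean correlations of their deviations from strain means were 0.0427, 0.00338 and 0.0199, so the numbers were not taken to pair arrays. As a hint from the data against this, 14 of 24 arrays correlated best with arrays of their own number. The replicate block left the counts within 1.5 times, with 2153 genes for sip1, 2256 for gal83 and 2100 for the triple strain against the reference. Counts not given below stayed within 1.5 times of the reported value under the alternatives run. A similar count can hold other genes. Without the 3 doubted arrays the triple strain had 716 calls against sip1 gal83, where 531 of the reported 717 were kept. Against sip2 gal83 it had 786, with 557 of the reported 789 kept. The sip2 gal83 strain had 1535 against the reference, with 1333 of 2031 kept. In these comparisons 0 calls turned to the opposite direction.

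With array weights the counts were 160 for sip1 sip2, 1594 for sip1 gal83 and 3392 for the triple strain against the reference, 2658, 2248 and 2026 for the triple strain against sip1 sip2, sip1 gal83 and sip2 gal83, 1372 for sip2 gal83 against sip1 gal83, and 161 and 490 for sip1 and gal83 against the other single deletion strains. With the compared groups alone they were 5 for sip1 sip2 and 528 for sip2 gal83 against the reference, 1109 and 232 for the triple strain against sip1 gal83 and sip2 gal83, 4 and 210 for sip2 gal83 against sip1 gal83 and sip1 sip2, and 35, 34 and 120 for sip1, sip2 and gal83 against the other singles. Leaving out the lowest 25% of genes gave 5 for sip1 sip2. Raising low values gave 52, 40 and 133 for the 3 single strains against the others, and quantile normalization 58 for sip2. Gene group calls numbered 0 with an estimated correlation and 113 with fry (18 higher and 95 lower), against 51 (26 and 25), and the 61 with quantile normalization were 18 higher and 43 lower. Of 61 called group results named in the text, interactions and strain contrasts included, 2 held with an estimated correlation. Raising low values ended 8 of the 61, and leaving out the 3 doubted arrays ended 5. Quantile normalization, array weights and the compared groups alone ended 4 each, and fry ended 2. The cause was not tested.

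Without the 3 doubted arrays the counts were 41 for sip1 sip2 and 898 for sip1 gal83 against the reference, 183 and 1091 for sip2 gal83 against sip1 gal83 and sip1 sip2, and 174, 201 and 330 for sip1, sip2 and gal83 against the other singles. Leaving out each replicate in turn gave 231 to 500 for sip1 gal83 against the reference, 379 to 766 and 492 to 1107 for the triple strain against sip1 gal83 and sip2 gal83, 189 to 1209 for sip2 gal83 against sip1 gal83, and 21 to 149, 26 to 120 and 95 to 259 for the 3 single strains against the others. The cause was not tested.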

Other observations

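The tests of a whole swap of samples and of the meiotic genes, the shares read from PHO5 and from genes at the floor, and the comparisons among single deletion strains, were chosen only after the results were seen.

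Beyond the carbon and meiotic genes, some amino acid and sulfur genes were higher in the triple strain, a minority of each group. Of 43 genes of amino acid synthesis under Gcn4 15 rose and 2 fell (15 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00489, or 0.867 with an estimated correlation). SER3 rose by 0.84 ± 0.056. The call of this group ended without reference replicate 3 (adjusted p = 0.077). Of 27 sulfate and methionine genes 8 rose (8 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00126, or 0.666 with an estimated correlation). MET22 rose by 0.70 ± 0.079. Of 27 genes of nitrogen source use 4 rose and 11 fell (4 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.393, or 0.932 with an estimated correlation). The GABA permease gene UGA4 rose by 2.60 ± 0.34, the arginase gene CAR1 rose by 2.01 ± 0.14 and the permease gene AGP1 rose by 1.76 ± 0.14. DAL2 fell by 1.37 ± 0.18. The low-affinity hexose transporter gene HXT1 rose by 2.24 ± 0.19 from 2.21 ± 0.00070, the lower end of the scale. Of 17 hexose transporter genes 6 rose and 1 fell (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0948, or 0.666 with an estimated correlation).

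The biotin precursor transporter gene BIO5 fell by 3.26 ± 0.60 in the sip2 gal83 strain and fell by 3.85 ± 0.60 in the triple strain. In sip2 gal83 13 of 23 genes for thiamine, biotin and other vitamins fell. Adjusted over the list alone, 0 were higher and 13 lower (camera adjusted p = 0.0124, or 0.666 with an estimated correlation). In the triple strain 8 fell and 1 rose (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.488, or 0.932 with an estimated correlation). The median of the group in the triple strain, -0.113, turned to 0.026 under quantile normalization.

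In the array labelled sip1 gal83 replicate 2, GAL83 stood at 9.72 and SIP2 at 8.48, and in the array labelled sip1 sip2 replicate 3, SIP2 stood at 6.0. Over 75 other genes that differ between these strains and lie above the floor in both, the first array held a median share of 0.353 of sip1 sip2 signal (95% interval 0.293 to 0.373), against 0.0666 and -0.0714 in the strain's other arrays. The second held 0.292 of sip1 gal83 signal (0.243 to 0.35), against -0.00983 and 0.00973. These intervals resample the genes of 1 array, which are not independent, and do not measure the spread between arrays. The other arrays also picked the 75 genes. Each of them was scored against the strain's remaining array, so their paired values nearly mirror each other. Mixing of cells or RNA between these strains may be a source, but single genes gave unequal shares: SIP2, GAL83 and PHO5 gave 0.571, 0.342 and 0.0622 in the first array and 0.0727, 0.216 and 0.327 in the second, and 7 genes at the floor in 1 strain, PHO5 among them, had medians of 0.0937 and 0.327. A swap of whole samples is argued against, since SIP2 in the first array lay 6.46 above its level in the other sip1 sip2 arrays.

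The rise of meiotic genes in the triple strain may reflect loss of the repression of the early meiotic class, a hypothesis that no test here takes to the proteins. The median change of 26 early genes exceeded that of 22 middle genes by 2.68 on the log2 scale, with 19 early genes higher and 1 lower. The early class was set up after early genes were seen to be high, so this difference restates that observation and does not test the hypothesis, which stays open. Cells in later sporulation are argued against by the median of 0.00223 for the middle genes (95% interval from resampling genes, -0.132 to 0.00474). A single outlying array is argued against too, since the early class stood 2.91, 3.02 and 1.47 above the reference in the 3 arrays.

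Meiotic regulators were looked up in the triple strain after the early genes were seen. The activator gene IME1 fell by 0.81 (adjusted p = 0.00278) and the repressor gene UME6 rose by 0.65 (adjusted p = 0.00327). The repressor genes RME1, SIN3 and RPD3 fell by 0.31, fell by 0.21 and fell by 0.17 (adjusted p = 0.0175, 0.0209 and 0.0428), and RIM15 fell by 0.19 (adjusted p = 0.0319). NDT80, for the activator of middle genes, stood at -0.25 and did not pass (adjusted p = 0.376). ISW2, another repressor gene, and IME4, at the floor, stood at -0.139 and 0.00377 and did not pass either (adjusted p = 0.231 and 0.893). In the array labelled sip2 gal83 replicate 1 the SD of the residuals was 0.294 and the array weight 0.0724, with no explanation tested.

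The count of genes that differ among the 8 strains, 3892, was reached by 1 of 100 regroupings of the 24 arrays, the real one, with 2172 the highest other, so chance can be excluded. For the gal83 strain against the other single deletion strains (204 genes, 1 of 100, highest other 68) the share is under 0.05 too. That comparison was chosen after the data were seen, and its count was 95 without gal83 replicate 1. For sip1 (79 genes, 4 of 100, highest other 177) the share is under 0.05, but a regrouping that called 177 genes points to a structure of the samples, and the count was 21 without sip1 replicate 2. Chance was not excluded for sip2 (100 genes, 5 of 100, highest other 172) or for the 51 gene group calls (63 of 100, highest other 85). These regroupings keep the real differences among strains, such as those of gal83, so their counts are not values without effects. For sip1, sip2 and the gene groups they therefore cannot decide. Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. There the real counts of 2148, 2217, 2243, 14, 594, 2031 and 2093 for the sip1, sip2, gal83, sip1 sip2, sip1 gal83, sip2 gal83 and triple strains against the reference stood beside highest others of 0, 0, 11, 12, 2, 2 and 2. Those of 1748, 717 and 789 for the triple strain against the double strains stood beside 1, 1 and 2, and those of 683 and 1663 for sip2 gal83 against sip1 gal83 and sip1 sip2 beside 3 and 81.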
